A study of Bacillus subtilis PY79 with 24 samples.

How the data were processed

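Hi-C contact maps were analysed for 24 libraries of Bacillus subtilis, a rod-shaped soil bacterium with a circular chromosome, from 4 strains of the PY79 background. Per the labels, every strain lacked its own spo0J gene, kept a single parS site at 1 degree to the left of the replication origin, and carried an IPTG-inducible spo0J at yvbJ. The strains differed in smc, which was wild type or carried R57A, K12R or F66Y. Cells grew in CH medium, a defined rich medium, and were fixed with 3% formaldehyde for 30 min. DNA was cut with HindIII, per the labels. Uninduced cells were grown at 22 °C without IPTG, and induced cells at 37 °C with 1 mM IPTG.

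The deposited values were a fraction of each bin's contacts, and the authors had balanced the maps before deposit: as measured here, each map was a symmetric table of 404 by 404 bins whose rows summed to between 0.998 and 1.002. Bowtie2 2.1.0 is named in the submitters' processing notes. The bin width, genome build, balancing method, filters and sequencing depth were not given in the sources used here. Distances were computed at 10 kb per bin, which gives a chromosome of 4040 kb. All kb values and rates scale with that assumption. The reference annotation at hand, ASM2352161v1 of the PY79 strain, would give bins 2.64% longer, so it was used only for gene names and neighbours, and no coordinate was taken from it. Bin 1 was taken to start at the origin, which put parS in bin 403. This choice rests on the label's position and on no header.

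Values had 4 decimals, and the rounding step of 0.0001 was 5.56% to 8.33% of a map's median value (0.0012 to 0.0018). Depth is unknown, so no counting interval was computed. The main diagonal and the first off-diagonal were 0 in every map, and the corner that joins the last bin to the first was removed here to match. No pair of libraries was a copy: the highest share of bin pairs with equal values between any 2 libraries was 16.3%.

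Observed contact was divided by the mean contact at the same arc length, over pairs whose midpoint lay more than 15 bins from parS and from the opposite point. The ratio of observed to expected contact was smoothed over 3 midpoints and 5 arc lengths. The ridge was the highest value within 15 midpoint bins of parS, and R was that maximum over the median of the same maximum in 10 equally wide windows elsewhere. The front was the end of the run of R of at least 1.5 that starts 100 kb from parS per arm, with gaps of up to 3 steps. With this definition, fixed before the data were examined, a front was found in only 3 of 24 maps, because R stayed below 1.5 close to parS. The fronts given in the report therefore come from one of the alternatives planned beforehand, in which each map was divided by the uninduced map of its strain. That choice was made after seeing that the first definition failed. A front measured so has no value of its own in the uninduced maps. On simulated maps with known fronts and 10% noise, 20 of 20 fronts were found with a largest error of 5 kb, and no front in maps without a ridge. The simulated ridge had a constant height and a sharp end, and both maps of a pair came from the same mean. Real ridges were graded: wild type at 20 min rose 2.16-fold at 250 to 500 kb and 1.28-fold at 500 to 1000 kb. The simulated error therefore does not carry over to the real fronts.

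The rate was the least-squares slope of the front on minutes with its residual SE, tested by exact permutation of fronts over time points. Zone scores were log2 of mean observed over mean expected contact within 5 midpoint bins of the line through parS. The 5 zones ran from 50 to 250, 250 to 500, 500 to 1000, 1000 to 1500 and 1500 to 1900 kb per arm. Induced and uninduced libraries were compared by exact permutation of which library of each strain is called uninduced (1296 arrangements). Wild type was compared with the mutants by exact permutation of strain names within 20, 30 and 40 min (64 arrangements), and each mutant with the other 2 within 20 to 60 min (243 arrangements). Such a permutation treats the libraries of a strain as independent, although they share 1 strain and, for fronts and changes, 1 uninduced map. Exchange of whole strains over all times was therefore added after the results were seen, with 4 arrangements for wild type and 3 for a mutant. All tests were two-sided, with Benjamini-Hochberg adjustment within each family.

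Insulation was log2 of the mean contact between the 10 bins on either side of a bin over its chromosome mean, so a low score marks a barrier. It was fitted with limma 3.58.1 in R 4.3.3 over 404 bins, with strain as a factor for induction and minute as a factor for wild type against mutants, at an adjusted p under 0.05. Neighbouring bins share contacts and are not independent, and the fit of wild type against mutants takes the libraries of a strain as independent too. In simulated data, 91.7% of 60 bins changed by 0.2 were recovered in the induction fit and 93.3% in the strain fit; for a change of 0.1 the shares were 18.3% and 11.7%. The simulated noise was independent between bins and libraries, and the changed bins were scattered at random. These shares therefore do not carry over to the real fits. Boundaries were local minima within 5 bins on each side, at least 0.2 below the mean. A recurrent boundary was found within 1 bin in at least 18 of 24 libraries. Other steps used Python 3.11.15 with numpy 2.4.6, and matplotlib 3.10.9.

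The regions named are those fixed beforehand: parS, the opposite point, recurrent boundaries, and for each limma contrast up to 10 bins with the largest change past the threshold and one sign in all strains. The planned test of gene lists at boundaries was not run, and yvbJ and smc were not placed on the maps, because no annotation of known matching build was at hand. Alternatives covered the threshold, smoothing, window, gaps, expected value, rebalancing, time points, strains left out, insulation window and boundary depth. Because balancing fixes each bin's total, low bins were found by contact within 3 bins of the diagonal.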

Results

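Contact maps from 24 Hi-C libraries followed the Bacillus subtilis chromosome after production of Spo0J was switched on. Hi-C joins and sequences DNA ends that lie close together in fixed cells, so each map value is a contact level between 2 stretches of the chromosome. Spo0J, a ParB protein, binds parS sites near the origin and loads the SMC condensin, a ring-shaped ATPase that brings the 2 chromosome arms together. Per the labels, each strain kept 1 parS site, at 1 degree left of the origin. In the reference annotation spo0J is followed by soj, its ParA partner, and lies 11 genes away from dnaA, the initiator of replication. The study's title asks for evidence in living cells that SMC moves along DNA by using its ATPase, and the design compared wild-type smc with R57A, K12R and F66Y.

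Each strain had 1 uninduced library and 5 induced ones. Wild type was sampled at 20, 25, 30, 35 and 40 min after IPTG, and the 3 mutants at 20, 30, 40, 50 and 60 min. There was 1 library per strain and time, so no value has a replicate error. Permutation p-values give the share of rearrangements of these libraries with a difference or slope at least as large. Limma p-values take libraries of different minutes as replicates. The maps hold balanced contact fractions, so their depth is unknown. Uninduced cells were also grown at 22 °C and induced cells at 37 °C, so every induced against uninduced difference below covers both changes.

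After induction, contact between equidistant loci of the arms was centred on parS. The anti-diagonal through each of the 404 bins was ranked by its contact over 50 to 500 kb per arm. The top centre lay within 5 bins of parS in 19 of 20 induced libraries and in 0 of 4 uninduced ones. The exception was K12R at 20 min, whose top centre was bin 225 and whose parS ranked 23. In the uninduced maps parS ranked between 240 and 333. At parS the wild-type score was -0.02 on the log2 scale without induction and 0.80 at 20 min. The K12R score was -0.17 without induction, 0.17 at 20 min and 0.82 at 60 min.

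Contact rose first near parS and later towards the terminus. Over 250 to 500 kb per arm, wild type was 2.16-fold above its uninduced map at 20 min and 2.62-fold at 40 min. Over 1000 to 1500 kb it was 0.954-fold at 20 min, 1.35-fold at 30 min and 1.96-fold at 40 min. R57A reached 3.12-fold at 250 to 500 kb and 2.40-fold at 1000 to 1500 kb by 60 min. K12R reached 2.72-fold and 1.84-fold in these zones, and F66Y 2.57-fold and 2.25-fold.

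Averaged over strains, the induced score exceeded the uninduced one by 0.64 at 50 to 250 kb, by 1.29 at 250 to 500 kb and by 0.92 at 500 to 1000 kb (log2). Each of these gave an adjusted p of 0.00129 by exact permutation, from a raw p of 0.000772, the smallest the design can give, and 20 of 20 induced libraries lay above their own uninduced map. At 1000 to 1500 kb the difference was 0.55 (adjusted exact permutation p = 0.0154), and at 1500 to 1900 kb it was 0.34 (adjusted exact permutation p = 0.0145), with 19 of 20 libraries above in each. The uninduced scores of the 4 strains had an SD of 0.06 to 0.09 per zone. The 1000 to 1500 kb call was lost without F66Y (0.48, adjusted exact permutation p = 0.0509).

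**Figure D1:**
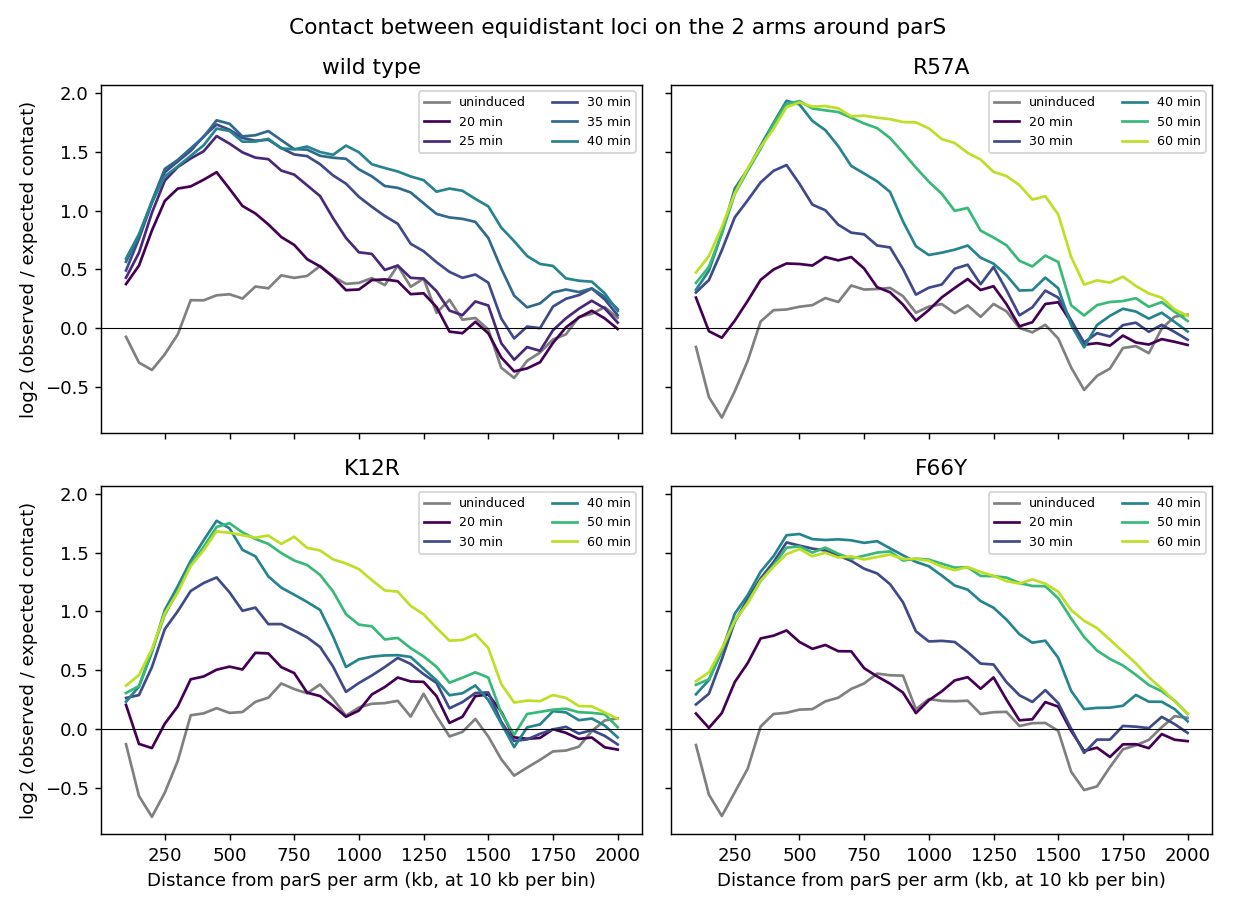
Contact between loci at equal distance on both sides of parS, as log2 of observed over expected contact (y axis) against distance per arm in kb (x axis), for each strain; lines are single libraries, grey for uninduced and coloured by minutes after IPTG. The raised stretch extends farther from parS at later times, and over 50 to 1900 kb the mean score of wild type is 0.50 at 20 min and 1.12 at 40 min.

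The front of juxtaposition, measured in each map relative to the uninduced map of its strain, moved away from parS in every strain. In wild type it lay at 555, 750, 1015, 1115 and 1775 kb per arm at the 5 times. In R57A it lay at 245, 595, 905, 1190 and 1780 kb, and in K12R at 150, 640, 810, 1020 and 1680 kb. In F66Y it lay at 380, 750, 1275, 1820 and 1870 kb. The slopes were 56.1 ± 10.3 kb per min per arm in wild type, 36.65 ± 3.06 in R57A, 34.4 ± 4.82 in K12R and 40.5 ± 4.89 in F66Y (residual SE, 5 time points each). Each slope had an adjusted exact permutation p of 0.0167, the smallest that 5 ordered times allow. The largest step was in wild type between 35 and 40 min, at 132 kb per min, and without the 40 min library the wild-type slope was 38.9 kb per min. The size of this step depends on the definition. The definition fixed beforehand gave 1525 kb at 35 min and 1670 kb at 40 min. The mean change within 5 midpoint bins of parS gave 1635 and 1765 kb.

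These slopes depend on how the front is defined. The definition fixed before the data were examined found a front in 3 maps only, all wild type, at 1255, 1525 and 1670 kb (30, 35 and 40 min). Without smoothing the wild-type slope was 17.2 kb per min, below the 38.3 of R57A, and with a half-height front it was 24 against 31.55. The slope over 20 to 40 min was 61 kb per min in wild type and 36.9 in the mutants on average, which did not pass an exact permutation test (p = 0.438).

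**Figure D2:**
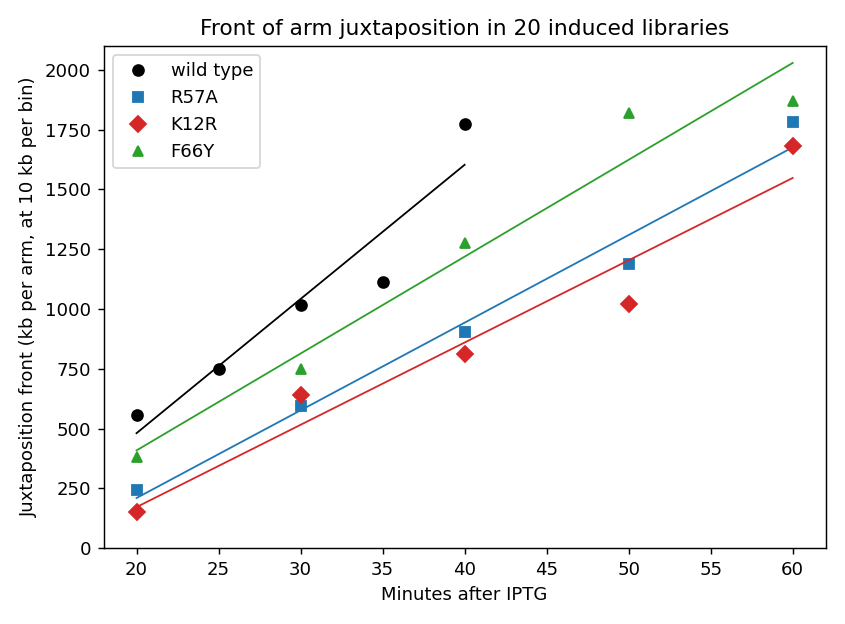
Distance of the juxtaposition front from parS in kb per arm (y axis) against minutes after IPTG (x axis); each point is 1 library, measured relative to the strain's uninduced map, and lines are least-squares fits per strain. At 20, 30 and 40 min the wild-type points (555, 1015 and 1775 kb) lie above those of all 3 mutants.

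Wild type was ahead of the mutants at matched times. Its front was farther from parS than that of every mutant at 3 of 3 shared minutes, with a mean of 1115 kb against 638.9 kb. The difference was 476.1 kb (exact permutation p = 0.0156, the smallest of 64 arrangements). With whole strains exchanged instead, 4 arrangements allow no exact permutation p below 0.25, which was reached (p = 0.25). Against single mutants the mean lead was 533.3 kb for R57A, 581.7 kb for K12R and 313.3 kb for F66Y, each with an exact permutation p of 0.25, the smallest that 3 pairs allow. The size of the lead over F66Y depends on the definition. By the mean change within 5 midpoint bins of parS, wild type lay at 665, 1120 and 1765 kb at these minutes. F66Y lay at 555, 1055 and 1710 kb by that definition, a smaller lag. The zone score over 50 to 1900 kb gave the same order, with 0.85 in wild type and 0.50 in the mutants (exact permutation p = 0.0156). Part of this was present without induction, where wild type scored 0.08 and the mutants between -0.09 and -0.07. As change from the uninduced map the difference fell from 0.35 to 0.19 (exact permutation p = 0.0156). Without smoothing the front difference was 167.2 kb, with wild type still above (exact permutation p = 0.0156), and with a half-height front it was 262.8 kb.

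Among the mutants, F66Y was ahead and K12R had the lowest mean ridge score over 50 to 1900 kb. The F66Y front was farthest at 5 of 5 times, with a mean of 1219 kb against 901.5 kb in the other 2 mutants (adjusted exact permutation p = 0.0123). K12R had a mean zone score of 0.59 against 0.73 in the other 2 (adjusted exact permutation p = 0.0370), and it was above both at 0 of 5 times. At 20 min K12R was level with R57A (0.176 in each). Over 250 to 500 kb alone, K12R was the lowest at 20 and 30 min only. At 40, 50 and 60 min F66Y was the lowest there, with 1.36, 1.28 and 1.26 against 1.45, 1.41 and 1.38 in K12R. The F66Y zone score was 0.76 against 0.64, above both at 4 of 5 times, which did not pass (adjusted exact permutation p = 0.0617) except without 60 min (0.13, adjusted exact permutation p = 0.0370). The K12R front averaged 860 kb against 1081 kb, which did not pass (adjusted exact permutation p = 0.0988). R57A did not stand apart in front (943 against 1039.5 kb, adjusted exact permutation p = 0.523) or in zone score (0.70 against 0.67, adjusted exact permutation p = 0.638). Pairs of mutants cannot give an exact permutation p below 0.0625, and exchange of whole strains none below 0.333. The F66Y call was lost without smoothing (65 kb) and its sign turned with a threshold of 2 (-248 kb) or a half-height front (-113.5 kb), and with a threshold of 2 R57A was ahead by 401.5 kb (adjusted exact permutation p = 0.0370); the K12R call was lost when any of the 30, 40, 50 or 60 min times was left out.

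Within the search window, the arms advanced by similar distances. The ridge was searched only within 15 midpoint bins of parS. This limits how unequal the arms could appear, most of all far from parS. Along the ridge, the distance on the right arm over that on the left arm had a mean of 1.03 ± 0.09 (SD, 18 libraries with a front of at least 300 kb). By strain it was 1.03 ± 0.03 in wild type, 1.04 ± 0.05 in R57A, 1.05 ± 0.07 in K12R and 0.984 ± 0.148 in F66Y. The lowest value, 0.722, was F66Y at 20 min, and the highest, 1.13, was K12R at 50 min. Moving parS by 1 bin to the right gave 0.994, so the mean cannot be set apart from equal arms. In each strain the median midpoint of the ridge lay farther right of parS at the last time than at the first. It went from -0.5 to 2 bins in wild type (20 to 40 min) and from -3 to 2 in F66Y (20 to 60 min). From 30 to 60 min it went from -1.5 to 3.5 bins in R57A and from -0.5 to 4 in K12R. The shift was not tested.

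Contact away from the parS line also differed between induced and uninduced maps. Shares were computed with pairs near the parS line left out. Contacts over 100 to 500 kb made up 39.3% of contact in induced maps and 44.4% in uninduced ones (adjusted exact permutation p = 0.00129). Those over 1000 kb made up 24.3% and 19.4% (adjusted exact permutation p = 0.00129), and those over 500 to 1000 kb 17.6% and 18.4% (adjusted exact permutation p = 0.0347). The share over 20 to 100 kb was 18.8% and 17.8%, which did not pass (adjusted exact permutation p = 0.117) except without F66Y (1.28 points, adjusted exact permutation p = 0.0417). The uninduced SD over 4 strains was 2.42 percentage points for 100 to 500 kb and 2.49 for over 1000 kb. Contact fell more steeply with distance in induced maps over 50 to 500 kb, with a log-log slope of -0.73 against -0.59 (adjusted exact permutation p = 0.00129). From 100 to 1000 kb the difference had the other sign and passed (0.079, adjusted exact permutation p = 0.0386), and the 500 to 1000 kb call was lost without wild type or without R57A. With pairs near the parS line kept in, the 500 to 1000 kb difference turned to 0.134 percentage points (adjusted exact permutation p = 0.755).

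Wild-type maps had more distant contact than mutant maps. At 20, 30 and 40 min contacts over 1000 kb made up 29.04% in wild type and 21.02% in the mutants, and contacts over 100 to 500 kb 35.1% and 41.9% (adjusted exact permutation p = 0.0156 for each, and p = 0.25 with whole strains exchanged). The uninduced maps differed likewise, with 23.1% over 1000 kb in wild type and 18.1% ± 0.37 (SD of 3 strains) in the mutants.

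Local insulation changed over much of the chromosome. By limma, 165 of 404 bins differed between induced and uninduced maps, 85 with a higher and 80 with a lower score, in 15 stretches of neighbouring bins. All 165 had one sign in the 4 strains, as had many bins that were not called. The bins were chosen on the same data, so the shared sign is no separate support. The largest change was in bin 353 (314 degrees clockwise from the origin), where the score fell from -0.05 to -0.35 (change -0.30 ± 0.06 SE, limma adjusted p = 0.000526). The named bins included its neighbours 351, 352, 354, 355 and 356, with changes between -0.27 and -0.21. Bins 397 and 398, close to parS, fell from 0.37 to 0.15 and from 0.43 to 0.21. Bins 170 and 171, at 151 degrees, rose from 0.08 to 0.28 (change 0.20 ± 0.06, limma adjusted p = 0.0110). The parS bin itself changed by -0.13 ± 0.04 (limma adjusted p = 0.0214), and the opposite bin by -0.03 ± 0.05 (limma adjusted p = 0.651). Without wild type the count was 72 bins, and with a window of 20 bins the 165 bins called were 50 higher and 115 lower.

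**Figure D3:**
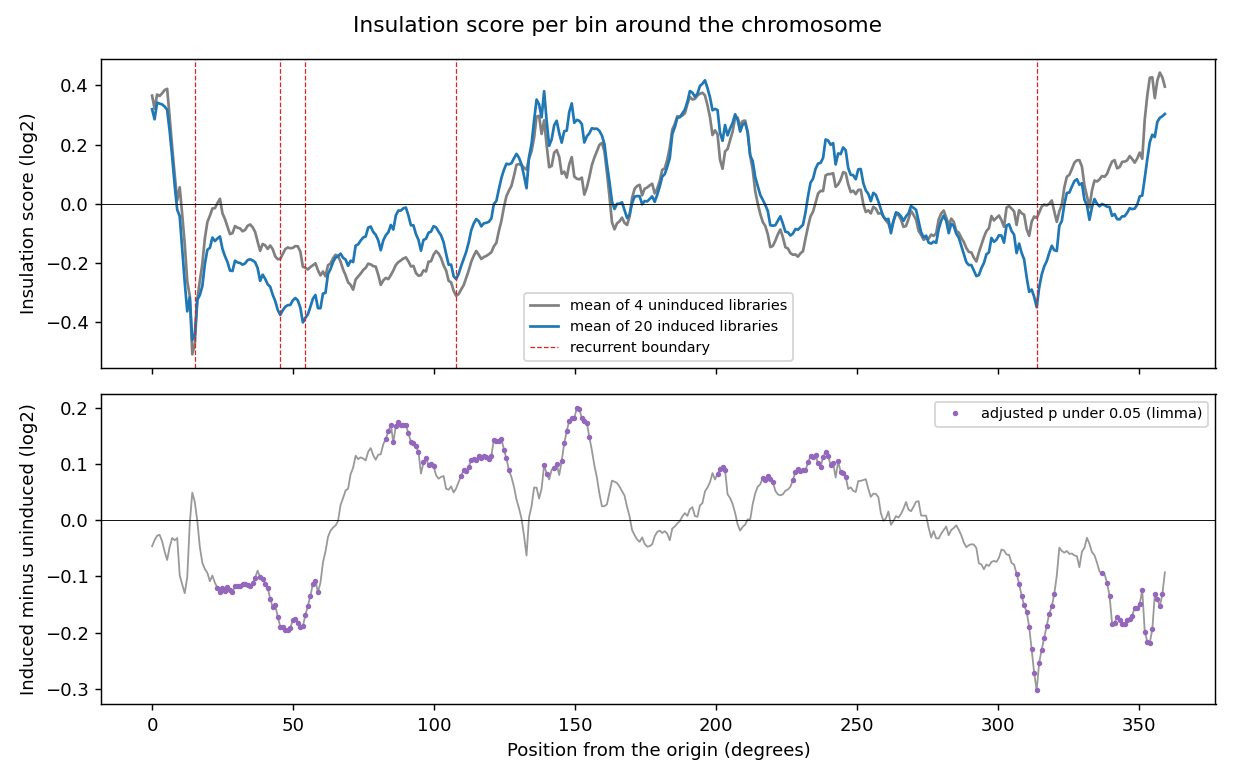
Insulation score per bin (upper panel, log2, mean of 4 uninduced and of 20 induced libraries, dashed lines at 5 recurrent boundaries) and the induced minus uninduced difference (lower panel, log2) against position in degrees from the origin. Points mark the 165 bins with a limma adjusted p under 0.05, and the lowest difference is -0.30 in bin 353.

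Wild type and mutants differed most near the terminus. At matched times, 193 of 404 bins differed by limma, 93 higher and 100 lower in wild type. The named bins were 188 to 197 (167 to 175 degrees), with a mean score of 0.14 in wild type and -0.12 in the mutants. Bin 192 had the largest difference, 0.29 ± 0.04 SE (limma adjusted p = 1.64e-07). In the uninduced maps the same 10 bins averaged 0.11 in wild type and -0.03 ± 0.02 (SD of 3 strains) in the mutants. Without K12R the count was 38 bins, without R57A 82, and relative to contacts within the sides 101; an exact permutation per bin called 0 bins after adjustment and 159 at an unadjusted p under 0.05, its smallest p being 0.0156.

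Chromosomal domains of bacteria are separated by boundaries across which contact is low. The maps had 5 recurrent boundaries, a count that ran from 1 (window of 20 bins or depth of 0.4) to 11 (window of 5 bins) in other settings. Bin 18, at 15.1 degrees, was a boundary in 24 of 24 libraries, with a mean score of -0.45 ± 0.09 (SD over 24 libraries). Bins 62, 52 and 122, at 54.4, 45.4 and 108 degrees, were boundaries in 21, 19 and 20 libraries, with scores of -0.36 ± 0.08, -0.35 ± 0.09 and -0.27 ± 0.06. Bin 353 was one in 18 libraries, at -0.30 ± 0.16. Induced maps had 8.6 boundaries on average and uninduced ones 6.75, which did not pass an exact permutation test (p = 0.144). With a depth of 0.1 the difference turned to -2.55 (exact permutation p = 0.00231).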

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

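All tests of explanations in this part were chosen after the results were seen. Strains differed after induction in 4 places. The front of wild type lay 476.1 kb ahead of the mutants at matched minutes, and the zone score over 50 to 1900 kb was higher by 0.35 on the log2 scale. That score is a level: wild type was already higher uninduced (0.08 against -0.09 to -0.07), and as change from the uninduced map the difference was 0.19. Among the mutants, the F66Y front was 317.5 kb ahead of the other 2, and the K12R zone score differed from that of the other 2 by -0.14. As change from the uninduced map the K12R difference was -0.15 (adjusted exact permutation p = 0.0123). Each passed an exact permutation of strain names within time, which takes the libraries of a strain as independent. With whole strains exchanged the design allows no exact permutation p below 0.25 for wild type or 0.333 for a mutant, so none could pass.

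The lead of wild type was weighed first. A uniform background that differs between maps keeps the order of contacts at a given distance, and reaches the rank front only through smoothing over neighbouring distances. The rank front is the end of the run in which the parS window exceeds all others. Searched from 100 kb it was found in 4 of 4 uninduced maps, and from 250 kb in 0 of 4. From 250 kb it was longest in wild type at 3 of 3 shared minutes (855, 1505 and 1615 kb), which argues against such a background as the whole cause. At 20 min F66Y had 670 kb, while R57A and K12R had no rank front and were counted as 250 kb. At 30 and 40 min the fronts were 855 and 955 kb in R57A, 885 and 945 kb in K12R, and 970 and 1515 kb in F66Y. Mutants were sampled every 10 min and wild type every 5, so the times below are interpolated, and the bound for excluding a later start was raised from 5 to 10 min after the values were seen. Between the zones at 500 to 1000 and 1000 to 1500 kb reaching a rise of 0.5, F66Y took -0.41 min relative to wild type. At rises of 0.4 to 0.8 the value ran from -0.67 to 0.50. The 500 to 1000 kb zone reached these rises 1.93 to 2.98 min later in F66Y than in wild type. A later start of the same movement would give such values, but they lie far below the 10 min step and do not settle it. At 20 min the 1000 to 1500 kb zone had changed by 0.14 in F66Y, 0.14 in R57A, 0.16 in K12R and -0.07 in wild type (log2). Such a head start can shorten the time between zones in each mutant. The F66Y front took 8.82 min from 600 to 1000 kb as reported, but 25.8 min without smoothing. Between the zones K12R took 11.5 min longer than wild type (7.64 to 11.5). Its reported front took 19.9 min from 600 to 1000 kb against 8.56 in wild type, and with a ridge search within 8 bins 19.7 against 7.76, but with a half-height front the times were 17.1 and 16.8 min. For R57A the extra time was 3.87 min (3.29 to 5.96). The R57A front took 13.2 min from 600 to 1000 kb as reported, longer than wild type. With a half-height front it took 14.1 min, less than wild type. In no mutant does the extra time between zones exceed the 10 min step at every rise. For each mutant the front times, or their order against wild type, depend on the definition. For each mutant a later start and slower movement therefore cannot be told apart. An effect of each smc allele stays open and rests on 1 strain per allele.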

How the results depend on the processing

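Of 329 recomputed values of 29 results, 231 kept their direction and their side of the threshold or stayed close to the main value. Fronts relative to the uninduced map under other definitions, runs from 250 kb, the band mean, and scores as change from uninduced were added after seeing the data. The cause of a change was not tested unless stated.

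The number of maps with a front was 3 as planned, 7 with a threshold of 1.3 (1 of them uninduced), 0 with 2, 1 with 5 by 9 smoothing, 1 without gaps, 9 for the half-height front, 13 by rank (4 of them uninduced), 20 relative to the uninduced map and 17 from 250 kb. Because no mutant or too few maps had a front in the map itself, most comparisons of fronts gave no value there.

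Rates (kb per min) were positive in all settings. With a time left out, exact permutation over 4 points gave p from 0.0417 to 0.125, since fewer points allow fewer orders; slopes ran from 38.9 to 63.5 in wild type, 31.45 to 38.4 in R57A, 27.8 to 37.0 in K12R and 37.7 to 48.45 in F66Y. The 20 to 40 min slopes (61, 33, 33 and 44.75, in that order of strains) rest on 3 points, with a smallest p of 0.333. Theil-Sen slopes over all 5 points were 49.5, 34, 33.8 and 41.04 and passed in none (adjusted exact permutation p = 0.117, 0.117, 0.117 and 0.0667). Slopes no longer past the threshold, mostly with fewer points, were as follows. In wild type they were 0.5 (threshold 2), 54.4 (no gaps), 51.4 (from 250 kb in the map itself), 41.5 (as planned, with the median or rebalanced), 39.4 (1.3 in the map itself), 93.7 (map itself unsmoothed) and 38.5 (map itself, 8 bins or half-height). In R57A they were 38.7 (threshold 2), 39.45 (no gaps), 38.4 (from 250 kb) and 31.8 (map itself). In K12R they were 33.1 (5 by 9), 33.5 (no gaps), 33.3 (from 250 kb) and 24.4 (map itself). In F66Y they were 68.75 (1.3), 37.65 (no gaps), 5.35 (half-height), 17.9 (map itself from 250 kb) and 44 (map itself, half-height).

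Wild type against mutants stayed above 0 wherever a value was obtained (a threshold of 2 gave none for the front): with a time or strain left out, 325.0 to 565.8 kb and 0.31 to 0.39 in score, where 2 times cannot pass; and 885 kb for the half-height front in the map itself. For F66Y the front difference became 65 kb (unsmoothed), -248 kb (threshold 2), -113.5 kb (half-height) and 536.5 kb (map itself, half-height); for R57A it became 401.5 kb (threshold 2), 134 kb (unsmoothed) and 134 kb (half-height). With a time left out the score difference ran from -0.17 to -0.12 in K12R, 0.094 to 0.13 in F66Y and -0.00422 to 0.047 in R57A.

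Against the 20 min maps alone, where 16 arrangements cannot pass, the zone differences were 0.42, 0.68, 0.23, 0.094 and 0.086 from parS outwards. With a strain left out the 1000 to 1500 kb value ran from 0.48 to 0.58. The induced minus uninduced difference in decay slope was 0.079 over 100 to 1000 kb (adjusted exact permutation p = 0.0386). With the parS line kept in, the share difference was -0.463 points at 20 to 100 kb and 0.134 at 500 to 1000 kb; with a strain left out these ran from 0.839 to 1.28 and from -0.966 to -0.621. The arm ratio was 0.985 unsmoothed and 0.994 with parS 1 bin to the right.

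With a strain left out, 72 to 130 bins changed with induction and 38 to 184 between wild type and mutants; the latter were 101 relative to contacts within the sides and 0 by exact permutation. Recurrent boundaries numbered 11 (window 5), 1 (window 20), 1 (depth 0.4) and 9 (12 libraries). The boundary difference was -0.4 (window 5) and -2.55 (depth 0.1). Rebalancing and a median expectation left front differences as they were. R compares windows at the same arc length and the maps were already balanced, so these settings could hardly change a front. They are counted among the values that held. The gene list test was not run. Unknown depth limits all values, and rounding limits the weakest contacts most.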

Other observations

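The tests of explanations for distant contact and for the decay were chosen after the results were seen, except the one on temperature and the counts over other choices of libraries. Boundaries differed in how often they were found with and without induction. Bin 353 was a boundary in 0 of 4 uninduced and 18 of 20 induced libraries, and bin 33 (28.5 degrees) in 0 of 4 and 11 of 20. Bin 62 was one in 1 of 4 and 20 of 20, and bin 52 in 1 of 4 and 18 of 20. In the other direction, bins 80 and 92 (70.4 and 81.1 degrees) were boundaries in 4 of 4 uninduced libraries and in 11 and 9 of 20 induced ones. Bins 33, 80 and 92 were chosen after their values were seen, and none of these frequencies was tested. The stretch from bin 381 to bin 403, which reaches parS, had a mean insulation change of -0.17, and the stretch from bin 44 to bin 67 one of -0.16.

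The number of boundaries per library was higher at the last time than at 20 min in each strain. Wild type had 9 at 20 min and 13 at 40 min, R57A 5 and 10 from 20 to 60 min, K12R 6 and 9, and F66Y 6 and 11. The trend was not tested.

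Decay over 50 to 500 kb was steeper in induced maps, and the change was already present at 20 min. From uninduced to 20 min the slope changed by -0.17 in wild type, -0.18 in R57A, -0.18 in K12R and -0.16 in F66Y, while the ridge score over 50 to 1900 kb changed by 0.42, 0.27, 0.25 and 0.31 in the same order. From 20 min to the last time the slope rose again by 0.076 ± 0.034 (SD, 4 strains) while the ridge grew, so the slope did not follow the ridge. Pairs near the parS line were left out of the slope, and in balanced maps growth of the ridge can alter the other contacts. These values therefore cannot decide whether arm juxtaposition itself is a cause. Growth at 37 °C instead of 22 °C may be the cause, but 0 libraries separate temperature from IPTG, so the 2 cannot be told apart.

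The larger share of distant contact in wild-type maps was compared with what a uniform background would give. A background of 14.9% ± 0.95 of the uninduced map, fitted to the share over 1000 kb, predicts 18.9% ± 0.46 (SD over 3 mutants) for 500 to 1000 kb, and 20.2% was found. The departure from the prediction was 2.96 SD there, 2.70 at 20 min, -3.21 at 30 min and -4.64 at 40 min. A background alone predicts a departure within the SD, which none of these maps gave. The values therefore argue against a background as the only difference. The SD holds no spread of wild-type maps, of which there was 1 per time, and the sign changed with time. A background together with other differences between these libraries stays open, as does an effect of the smc allele, which was not tested.

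The insulation counts were set against other choices of libraries. Calling 1 library per strain uninduced in 99 other ways gave at most 154 bins, against 165 for the real choice. Only 1 of 100 choices, the real one, reached the real count, which makes chance unlikely but does not exclude it. The libraries of a strain are minutes of 1 time course and are not independent. The choice with 154 bins kept 3 of the 4 uninduced libraries, and the 47 choices that kept none gave at most 44. For wild type against mutants, 1 of 64 choices reached 193 bins, the highest other being 160, which kept wild type at 2 of 3 minutes; the 27 choices without wild type gave 0 bins. The share set beforehand was met, but these choices mix libraries of different strains, which are not independent within a strain. Whole strains leave 4 choices, too few for a share under 0.05, with 193 bins for wild type and 0 for each mutant. Of the 193 bins, 141 had the same sign in the uninduced maps of wild type and mutants.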
